A study of Cyanobacterium with 24 samples.

How the data were processed

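The series holds 24 RNA-seq libraries of the cyanobacterium Synechocystis, from the wild type (wt) and from a strain called kai in the labels, which lacks the kaiABC gene cluster of the circadian clock. Per the labels, cultures grown in continuous light were shifted to darkness and later back to light, and total RNA was depleted of ribosomal RNA before TruSeq library preparation. Each strain was sampled at 6 times, in darkness at ZT 0.5, 5.5 and 11.5 and in the following light period at ZT 12.5, 17.5 and 23.5, where ZT counts hours from the start of darkness. Every one of the 12 groups holds 2 biological replicates. Strain, time and replicate were taken from the labels, and 0 columns were left unmatched.

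The deposited table gives 5265 features by 24 columns, and its unit is a normalised signal: the authors divided the read counts of each library by a single size factor. Column names begin with RAW, but every value of a library is a whole multiple of a single step, and dividing by that step gave whole reads for 100% of values at a tolerance of 0.001. Size factors recomputed with DESeq2 from these reads equalled the deposited ones, with a ratio of 1 in each library. The submitters name bedtools, HTSeq 0.6.0 and DESeq2 without giving their roles. Aligner, genome build and strandedness are not stated, so reads on opposite strands or from overlapping genes cannot be told apart, and no coordinates are given for any gene. Features include protein-coding genes, antisense RNAs and other non-coding RNAs, and 529 of them, with 6% of all reads, carry no gene name.

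Values were tested as log2 of the normalised count plus 1 with limma 3.58.1 (trend) in R 4.3.3, in a single fit of 12 group means over all 24 libraries. The 3773 features with a mean of at least 10 normalised counts were tested, of which 3227 are protein-coding. The comparisons were kai against wt at each of the 6 times, kai against wt over all times (the mean of the 6 differences), ZT 12.5 against ZT 11.5 in each strain (the lights-on response), ZT 11.5 against ZT 0.5 in each strain (the dark course), the differences between the strains in these responses, and F tests of the strain by time interaction and of time in each strain. Tests are two-sided except for Fisher's exact test, which is one-sided for more shared features than expected, and p values were adjusted with the Benjamini-Hochberg method over all features tested, and the threshold was 0.05. Group values are means of normalised counts with their standard deviation (SD, n = 2), log2 fold changes come from the fit with their standard error (SE), and a fold is 2 raised to that value.

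A total of 23 gene lists with 344 members were written from knowledge of this organism, and all 344 members were found in the table. They cover the photosystems, phycobilisome, electron carriers, ATP synthase, Rubisco and carboxysome, inducible inorganic carbon uptake, NDH-1, oxidases, sugar catabolism, hydrogenase, ribosomal proteins, pigment synthesis, pili, sigma factors, chaperones, photoprotection, dark-induced and light-repressed genes (the dark-induced list), nitrogen, phosphate, iron, and the deleted and remaining clock genes. Lists can share genes. The dark-induced list shares hspA with chaperones, sigB with sigma factors and isiA with iron. The carbon uptake list also holds flv2, flv4 and sll0218. Many of its members are neighbours by locus tag, so they are not independent. Lists with at least 5 tested members (22 of them) were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; adjusted p values of lists are Benjamini-Hochberg values over the lists within a comparison. Functional categories given in the table and locus-tag series (7000 for genes of the plasmid pSYSA, 5000 for pSYSM) were tested for enrichment with Fisher's exact test among the 3227 tested protein-coding genes.

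Genes named in the text follow a rule. It takes the deleted and remaining clock genes always, and for kai against wt over all times the 12 highest and 12 lowest protein-coding genes past the threshold with a mean of at least 50 in the higher strain and the same sign at 5 or more of the 6 times. For each other comparison it takes the 6 highest and 6 lowest with a mean of at least 50, for each list described the 2 to 4 members with the smallest adjusted p, and for F tests the 6 largest F. Non-coding features are summarised by count, with the 3 of smallest adjusted p named. Lists, rule, tests and most alternatives were chosen before the data were examined. Total-count scaling, which divides each library by its total reads (CPM), and leaving out the kai libraries of ZT 5.5 and ZT 11.5 were chosen after seeing the data.

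Alternatives were a pseudocount of 0.5 or 8, no filter or a filter of 50, upper-quartile and quantile rescaling, replicate as a block, culture as a random block, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, only the 4 libraries of a time, and leaving out each library in turn. Where a library is left out, the lone sample of its group is assumed to vary like the other groups. The fits were tested on simulated data with no strain difference and with known 2-fold or 4-fold changes. In these data the spread of a feature beyond counting noise was the same in all groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

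Library depth ranged from 1376979 to 18315808 reads. A group at 0 reads was given a floor of 3 reads per library, and a fold against it is a lower bound computed from the mean of the floors of its libraries. In the kai libraries of ZT 11.5 these floors are 53.3 and 48.2 normalised counts. Floors cover counting error only, since PCR copies of a molecule are not independent. With 2 replicates per group, p values of the main fit rest on a single spread per feature, pooled over all 12 groups of these samples. The spread was unequal. The median absolute log2 difference between replicates was 0.88 in kai at ZT 11.5 and 0.296 in kai at ZT 12.5. Pooling makes calls easier where the spread is wide and harder where it is narrow.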

Results

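RNA levels of 5265 features were measured in 24 libraries of Synechocystis, a cyanobacterium that stores glycogen in light and consumes it in darkness. The strains were the wild type (wt) and kai, from which the kaiABC cluster of clock genes was deleted, and each of the 12 groups of strain and time held 2 replicates. Darkness covered ZT 0.5, 5.5 and 11.5, and light covered ZT 12.5, 17.5 and 23.5. In wt the replicates had 9442191 and 11839143 reads at ZT 0.5, 6683533 and 5635836 at ZT 5.5, and 3950296 and 7472276 at ZT 11.5. In light the wt libraries had 15119561 and 18109165 reads at ZT 12.5, 12648012 and 17744894 at ZT 17.5, and 15034625 and 18315808 at ZT 23.5. The kai libraries of the dark period had 10384663 and 10457340 reads at ZT 0.5, 5951434 and 5814472 at ZT 5.5, and 1376979 and 1839505 at ZT 11.5. In light they had 9847977 and 15793252 reads at ZT 12.5, 16826247 and 17241612 at ZT 17.5, and 16103318 and 3116059 at ZT 23.5.

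A few features took most of the reads late in darkness. The 10 most abundant features held 69.8% ± 3.96 (SD, n = 2) of the reads in kai and 55.4% ± 3.25 in wt at ZT 11.5, but 29.8% ± 2.19 and 28.9% ± 2.47 at ZT 12.5. A set of 317 annotated non-coding RNAs held 35.5% ± 3.32 of the reads in wt and 21.9% ± 6.65 in kai at ZT 11.5, and 2% and 3.1% at ZT 12.5. A single RNA of this set took 24.9% and 26.9% of the reads in the wt libraries of ZT 11.5, and 8.8% and 11.2% in those of kai. On average 2640.5 features had 0 reads in kai at ZT 11.5 and 1609.5 in wt. A single read of the kai libraries at ZT 11.5 stands for 17.75 and 16.06 normalised counts, so low levels were not measurable there. Replicates correlated least in kai at ZT 11.5, with Pearson's r across features of 0.716, and in kai at ZT 5.5 with 0.768.

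**Figure D1:**
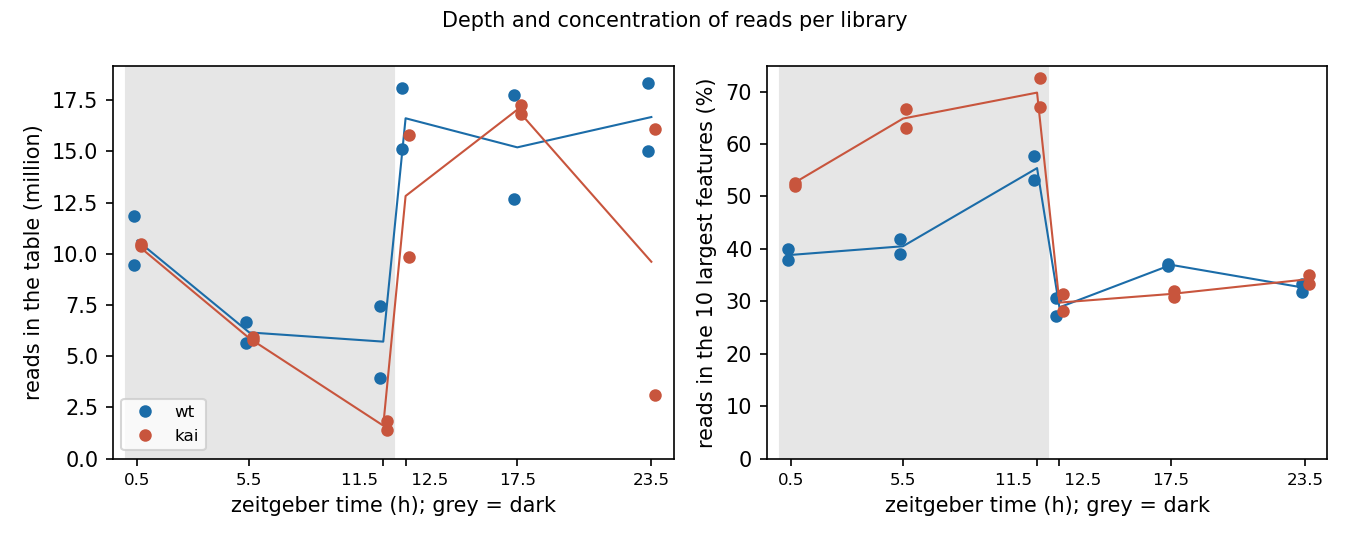
Reads per library (left, labelled in 1e6 reads) and percent of reads in the 10 largest features (right) by zeitgeber time in hours, with points for the 2 libraries of each group, lines for their means and grey for darkness. The kai libraries of ZT 11.5 are the smallest, with 1376979 and 1839505 reads, and put 69.8% of them in 10 features.

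The deleted genes kaiA, kaiB1 and kaiC1 encode the core oscillator. In wt all of them peaked at ZT 12.5, the first time sampled in light. There kaiA reached 2621.6 and 2335.6 normalised counts, kaiC1 2038.4 and 3262, and kaiB1 270.9 and 283.2. Over all 12 libraries of each strain kaiA averaged 766 ± 806 (SD) in wt and 54.7 ± 107 in kai, kaiB1 74.9 ± 97.3 and 7.68 ± 22.7, and kaiC1 705 ± 962 and 8.60 ± 14.4. The kai libraries held 433 reads of kaiA, 45 of kaiB1 and 177 of kaiC1, against 22230, 2494 and 23301 reads in wt. Over all times the log2 fold change of kai against wt was -4.78 ± 0.62 (SE) for kaiA, -4.14 ± 0.69 for kaiB1 and -6.57 ± 0.53 for kaiC1 (limma, Benjamini-Hochberg adjusted p = 2.51e-05, 0.000267 and 1.29e-07). kaiC1 was past the threshold at all 6 times, though this call was lost at ZT 17.5 (adjusted p = 0.0556 to 0.218) and ZT 23.5 (0.0835 to 0.293) without any single library of that time, and at ZT 0.5 without replicate 2 of either strain (0.0567). Replicate 1 of kai at ZT 5.5 departed from the other kai libraries, with 388.73 normalised counts (118 reads) of kaiA and 79.06 (24 reads) of kaiB1, yet 0 reads of kaiC1; wt at this time had 500.11 and 407.05 for kaiA, and 7.4 and 13.52 for kaiB1, less than this kai library. No other kai library exceeded 60.67 for kaiA.

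**Figure D2:**
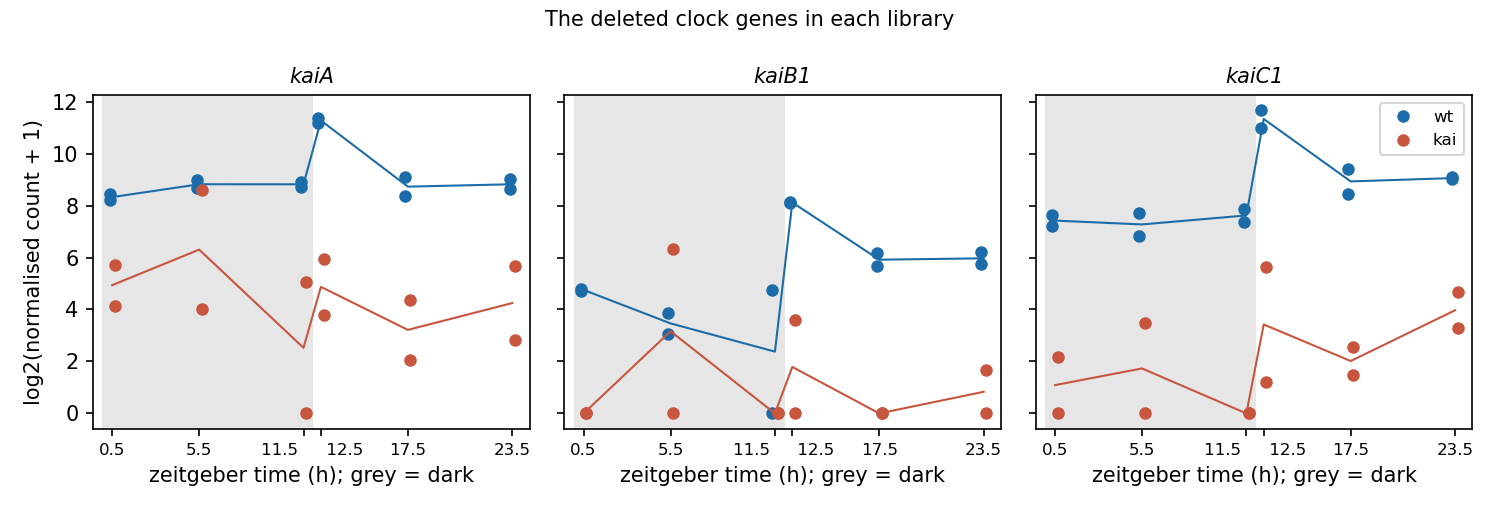
Log2 of the normalised count plus 1 of kaiA, kaiB1 and kaiC1 in each of the 24 libraries by zeitgeber time in hours, with lines for the group means and grey for darkness. Levels in wt peak at ZT 12.5, where kaiC1 reaches 2038.4 and 3262 normalised counts.

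Other clock genes changed less. The kinase gene sasA, which reads out the oscillator, was higher in kai over all times by 0.36 ± 0.124 on the log2 scale (adjusted p = 0.034), and -0.32 with total-count scaling, which moved the median of all features from -0.43 to -1.01. Leaving out any of 12 single libraries raised the adjusted p of sasA to between 0.0507 and 0.0733. Lower over all times were cikA, a kinase that resets the clock, at -2.02 ± 0.558 (adjusted p = 0.011), and kaiB3 at -1.29 ± 0.324 (adjusted p = 0.0061), which became 0.087 after quantile rescaling. The response regulator genes rpaA and rpaB and the homologues kaiC2, kaiC3 and kaiA3 were not past the threshold over all times. At single times kaiA3 was lower at ZT 0.5 (471 against 2014 normalised counts, log2 fold change -2.11 ± 0.558, adjusted p = 0.023) and rpaB at ZT 5.5 (592 against 1309, -1.16 ± 0.347, adjusted p = 0.022). The kaiA3 call was lost without any of its 4 libraries (adjusted p = 0.071 to 0.13), and that of rpaB without either wt library or kai replicate 1 (0.0653 to 0.129). At ZT 11.5 cikA stood at 71 ± 100.4 (SD) in kai, from 8 reads, and 651 ± 55.1 in wt (adjusted p = 0.0031), and kaiB3 at 0 reads in kai and 33.9 normalised counts in wt, under the floor of kai, so a difference in kaiB3 was not measurable there. Also past the threshold at ZT 11.5 were rpaA and kaiC2 (adjusted p = 0.010 and 0.016; edgeR 0.067 and 0.12), but each rests on 1 read in kai. In wt they were at 59.3 ± 48.7 and 49.6 ± 18.7 normalised counts, close to the floors of 53.3 and 48.2 in kai. The rpaA call was lost without replicate 1 of wt or kai (0.103 and 0.132). That of kaiC2 was lost without wt replicate 2 or kai replicate 1 (0.0827 and 0.207). The value of kaiB3 over all times rests on the late dark libraries: without the kai libraries of ZT 5.5 and ZT 11.5 it was -0.36 (adjusted p = 0.54).

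The strains were compared at each time in darkness and in light. No complemented strain and no other mutant was sampled. Any other difference between the strains therefore cannot be told apart from the loss of the kaiABC cluster. In the fit of all libraries, 414 features were past the threshold at ZT 0.5, 1002 at ZT 5.5 and 1575 at ZT 11.5, then 219, 32 and 121 at ZT 12.5, 17.5 and 23.5. edgeR called 503, 885, 1225, 288, 77 and 156 at these times. The order of the times depended on the fit: with only the 4 libraries of a time the counts were 765, 661, 572, 1032, 72 and 37, and total-count scaling gave 2222 at ZT 5.5 and 1998 at ZT 11.5. The strain by time interaction was past the threshold for 1131 features (1104 with edgeR), 995 of them protein-coding, led by cmpC (F = 155.67, adjusted p = 2.42e-09), ndhD3 (F = 144.67), slr1076, slr1821, psaA and porB. Without replicate 1 or 2 of kai at ZT 11.5 the interaction count was 1729 or 1756. Power was limited: in simulated data limma recovered 15% to 35% of 4-fold strain differences at a single time and 80% over all times. It called 25% and 39% of 4-fold lights-on changes in wt and kai, counted in either direction. The power for the dark course was not simulated. At ZT 11.5 limma also made 111 false calls, 106 of them lower, where edgeR made 0. The simulation gave each feature the same spread beyond counting noise in all groups. These numbers therefore do not cover any wider spread of the replicates in kai at ZT 11.5.

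Scaling sets the balance of higher and lower calls. With the deposited factors the median log2 fold change of all features was -0.30 at ZT 0.5, -0.62 at ZT 5.5, -0.76 at ZT 11.5 and -0.43 over all times. Total-count scaling moved it to -1.01, -2.18, -1.80 and -1.01, and quantile rescaling to -0.02, -0.08, -0.04 and -0.03. camera tests a list relative to the other features. Of 104 calls of a list in a comparison, the list median changed sign in 18 under total-count scaling and in 3 after quantile rescaling, and in 0 under upper-quartile scaling, edgeR or DESeq2. The 18 follow from the shift of the median, since total-count scaling moves all features of a library by the same factor. Relative to the median of all features, 0 lists changed sign under it, as its construction implies, and 3 after quantile rescaling.

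**Figure D3:**
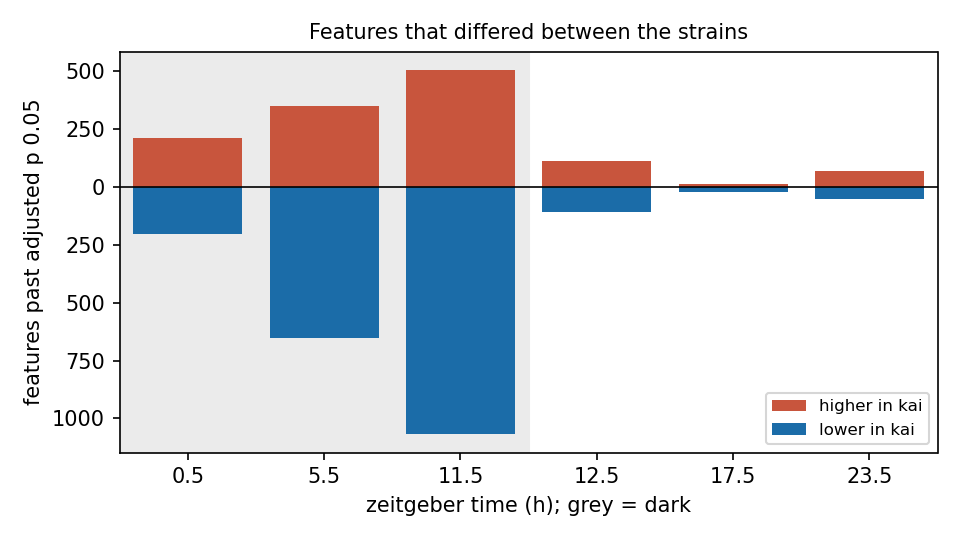
Features past the threshold (vertical axis, higher in kai upward and lower in kai downward) by zeitgeber time in hours, from limma at an adjusted p of 0.05. Counts rise from 414 at ZT 0.5 to 1575 at ZT 11.5 and fall to 32 at ZT 17.5.

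Soon after the shift to darkness, kai had higher levels of carbon uptake, ribosomal protein and photosystem I genes. Genes of the inducible inorganic carbon uptake list, which cells express when carbon is scarce, were higher. Among them were ndhD3 (6.60-fold) and cupA (6.79-fold) of the CO2-hydrating NDH-1 complex, and the flavodiiron gene flv2 (5.48-fold), which the list also holds. Ribosomal protein genes such as rpl2 (5.82-fold) and rpl22 (5.08-fold) and the photosystem I core genes psaA (2.58-fold) and psaB (2.30-fold) were higher too, although psaB turned to -0.53 on the log2 scale after quantile rescaling. Genes of phosphate acquisition were lower, with pstS1 at 3.77-fold and the alkaline phosphatase phoA at 4.46-fold. The glycolytic genes pfkA1 (7.22-fold) and gap1 (2.87-fold) and the gene of the sigma factor SigE, which drives sugar catabolism, were lower (sigE 5.24-fold). The widest differences were in neighbouring locus tags of the 5000 series: the sulfide-quinone reductase gene sll5036 averaged 16649 ± 132 (SD, n = 2) in kai and 155.6 ± 20.2 in wt (107-fold, adjusted p = 2.17e-06), and sll5035, slr5037, slr5038, sll5034 and sll5033 were 152-, 114-, 71.7-, 65.0- and 19.7-fold higher. At the low end, ssr0330 for ferredoxin-thioredoxin reductase was at least 14.2-fold lower, and sll1552, sll0742 and pstS2 averaged 1.78, 4.19 and 3.53 in kai against 313, 115 and 104 in wt.

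Of the 414 features at ZT 0.5, 210 were higher and 204 lower in kai, and 371 were also called by edgeR. Non-coding features made up 8 of the higher and 33 of the lower. Of the lower ones, 31 had 0 reads in both kai libraries. The share of higher calls was 50.7%, and 10.6% with total-count scaling. Without wt replicate 1 or 2 the count was 123 or 135, and without kai replicate 1 or 2 it was 237 or 225. Single calls lost in this way were ssr0330 without any of the 4 libraries (adjusted p = 0.092 to 0.154), gap1 and sll0742 without any but kai replicate 2 (0.0655 to 0.0923 and 0.0788 to 0.136), pstS2 without any but kai replicate 1 (0.158 to 0.273), phoA without replicate 2 of either strain (0.0502 and 0.0561), and sigE without replicate 1 of either (0.0646 and 0.0761).

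Among lists at ZT 0.5, carbon uptake had 8 of 14 tested genes higher and 0 lower, with 9 higher when adjusted over the list alone (median log2 fold change 1.65, camera adjusted p = 2.75e-12). Of 49 ribosomal protein genes 17 rose and 3 fell, 19 and 6 adjusted over the list alone (median 0.80, 2.59e-05). Photosystem I had 5 of 12 higher by either adjustment (median 0.79), NDH-1 6 of 16 higher and 1 lower, 7 and 1 over the list alone (median 1.16), and phosphate acquisition 4 of 11 lower, 6 over the list alone (median -1.47, adjusted p = 0.0017). Chaperones, with clpB1 4.24-fold and hspA 6.58-fold higher, had 4 of 11 higher (median 0.63, or -0.11 with total-count scaling), and nitrogen assimilation, with gltS at 7.79-fold, 2 of 19 (median 0.50, or -0.24). These 7 lists also passed with an estimated correlation. Calls lost with it were ATP synthase (1 of 10 higher, adjusted p = 0.12), phycobilisome (2 of 15, 0.055), photosystem II (4 of 26, 0.32; also lost without kai replicate 1, camera 0.108) and the dark-induced genes (1 of 5, 0.069). Sugar catabolism had 1 of 21 higher and 5 lower, and was not past the threshold as a list (0.14).

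After 5.5 h of darkness, all 14 carbon uptake genes were higher in kai, among them the bicarbonate transporter genes cmpC (42.3-fold) and cmpD (8128 against 56.9 normalised counts, 148-fold, adjusted p = 3.44e-10), ndhD3 (33.2-fold) and the porin gene porB (43.8-fold). The photosynthesis genes psaA (9.90-fold), psaB (10.6-fold), psbA2 (21.5-fold) and cpcA (6.82-fold, but -0.10 on the log2 scale after quantile rescaling) were higher. Against them, photosystem I had 1 gene lower, photosystem II 2 and cytochrome b6f and carriers 3. Higher as well were gifA and gifB, which encode inhibitors of glutamine synthetase (gifA 34.3-fold). All 5 genes of the dark-induced list were higher, including hspA (10.8-fold) and lrtA (11.99-fold). In wt from ZT 0.5 to ZT 11.5, hspA and isiA of this list rose 44.6- and 6.13-fold, but lrtA fell 3.63-fold. The manganese transport gene sll1598, which encodes the binding protein MntC, was higher, at 7988 ± 968 against 102 ± 6.76 (77.3-fold, adjusted p = 2.78e-06). The gene sll0218 of the carbon uptake list, between flv4 and flv2 by locus tag, was 153-fold higher and slr1087 62.7-fold, and slr2010 was at least 19.9-fold higher. Lower in kai were slr7098, at 11.5 against 967, and slr1712, slr0114, sll0688, sll0271 and slr0624, which had 0 reads in kai and were at least 18.9-, 13.8-, 12.6-, 12.2- and 10.2-fold lower.

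At ZT 5.5, 349 features were higher and 653 lower, with 39 and 119 non-coding ones among them; edgeR called 342 and 543, and 811 were shared. Of the lower features, 281 had 0 reads in both kai libraries. Higher calls made up 34.8%, which became 46.4% after quantile rescaling and 4.9% with total-count scaling. Leaving out wt replicate 1 or 2 gave 592 features each. The carbon uptake list had a median of 4.57 (14 higher adjusted over the list alone, camera adjusted p = 2.14e-25, 0.0010 with an estimated correlation) and the dark-induced list a median of 2.29 (5 of 5, 1.69e-05, 0.014). Photosystem I had 5 of 12 higher and 1 lower, 6 and 1 over the list alone (median 0.88, or -0.71 with total-count scaling; 0.00074 and 0.014). Chaperones, with dnaK2 at 6.32-fold, had 4 of 11 higher (median 0.51, or -1.18; 0.0019), a call lost with an estimated correlation (adjusted p = 0.089). The phycobilisome list had a negative median of -0.16 but a positive mean of 0.28 and test direction (5 of 15 higher, 1 lower, adjusted p = 0.051). Photosystem II had 7 of 26 higher and 2 lower (adjusted p = 0.051), and cytochrome b6f and carriers 1 of 11 higher and 3 lower (0.83). Phosphate acquisition had 5 of 11 lower and oxidases 2 of 8. None of these 4 lists was past the threshold.

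At the end of darkness, all 14 carbon uptake genes were higher in kai again, with cmpC at 83.8-fold, cmpD at 78.5-fold, porB at 60.8-fold and ndhD3 at 29.9-fold. Photosystem and antenna genes psaA and psaB (13.3-fold each), psbA2 (22.1-fold), psbC (9.89-fold), cpcA (11.5-fold) and cpcD (17.6-fold) were higher, although the phycobilisome and photosystem II lists, with 3 genes lower each, lost the call with an estimated correlation (adjusted p = 0.13 and 0.55). Higher too were atpD of the ATP synthase (13.2-fold), the ferredoxin gene petF (43.9-fold) and the protease gene ftsH2 (17.0-fold). Of the genes that break down glycogen and sugars, glgP1 (5.36-fold), opcA (6.89-fold), pgi (6.91-fold) and gap1 (at least 2.86-fold) were lower. So were 1069 of all 3773 features, and the list was not past the threshold (adjusted p = 0.15). The highest folds were those of sll0218 (454-fold) and slr1087, at 15827 ± 469 against 62.9 ± 65.6 (360-fold); slr2007, sll5067 and slr0529 were at least 64.2-, 54.1- and 43.4-fold higher. The lowest all had 0 reads in kai: sll0740, the beta-lactamase gene slr0319, slr1821, sll0867, sigI and slr5118 were at least 14.97-, 11.05-, 9.54-, 8.08-, 7.88- and 6.52-fold lower.

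At ZT 11.5, 506 features were higher and 1069 lower, 77 and 152 of them non-coding; edgeR called 472 and 753, with 1120 shared. Many lower calls rest on missing reads: 430 had 0 reads in both kai libraries, and for 207 of these the wt level was itself under the floor. Higher calls made up 32.1%, which became 44.9% after quantile rescaling, 47.4% with DESeq2 and 11.3% with total-count scaling. Besides carbon uptake (median 4.95, 14 of 14 over the list alone, camera adjusted p = 1.09e-18), photosystem I passed with either correlation (6 of 12 higher and 1 lower, 6 and 2 over the list alone, median 0.82, or -0.43 with total-count scaling; 0.0059 and 0.045). ATP synthase (5 of 10 higher, median 1.15, or -0.097), phycobilisome (6 higher and 3 lower of 15, median 0.90, or -0.034), photosystem II (6 and 3 of 26, median 0.65, or 0.45 with genes at 0 reads set to their bound, or -0.56 with total-count scaling) and the dark-induced genes (4 of 5, median 1.07, or -0.18) lost the call with an estimated correlation (adjusted p = 0.23, 0.13, 0.55 and 0.13). With camera it was lost for phycobilisome without kai replicate 2 (0.104), photosystem II without kai replicate 1 or wt replicate 2 (0.129 and 0.155) and the dark-induced genes without kai replicate 1 (0.0736). Sugar catabolism had 9 of 21 lower and 0 higher (median -1.66, or -0.97 with genes at their bound), ribosomal proteins 8 higher and 17 lower of 49, NDH-1 3 and 6 of 16, pili 3 and 10 of 34, oxidases 0 and 4 of 8, hydrogenase 0 and 3 of 5 and cytochrome b6f and carriers 2 and 4 of 11. None of these 7 lists was past the threshold.

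At the first time sampled in light, the difference in carbon uptake had turned around. Genes of bicarbonate transport, sbtA (7.12-fold), its regulator sbtB (8.67-fold) and cmpA (8.90-fold), and ndhD3 (3.59-fold) were lower in kai. Lower as well were atpA (4.03-fold), apcA of the phycobilisome core (2.72-fold), rbcL of Rubisco (2.55-fold), ccmM of the carboxysome (2.66-fold) and rpl10 (2.25-fold). Chaperone genes were higher: clpB1 averaged 46214 ± 3878 against 2999 ± 425 (15.5-fold), and dnaK2, htpG and hspA were 7.65-, 5.98- and 9.57-fold higher. The stress sigma factor gene sigB was at 22729 ± 3238 against 1485 ± 517 (15.7-fold, adjusted p = 8.57e-08), slr1603 at 58673 ± 10049 against 3100 ± 511 (18.9-fold), slr1667 was 25.2-fold higher, and slr1285 and slr1915 rose by log2 fold changes of 3.96 and 3.57. The gene ocp, which encodes the carotenoid protein that quenches light energy in the antenna, was 4.50-fold higher. Apart from the deleted clock genes, slr5053, ssl5045 and slr5056 were lowest, the last at 1586 ± 1182 against 38997 ± 937 (28.9-fold, adjusted p = 0.000157).

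At ZT 12.5, 111 features were higher and 108 lower, 8 and 3 of them non-coding; edgeR called 175 and 113, with 199 shared. The higher share of 50.7% became 63.9% with upper-quartile scaling and 60.8% with edgeR. Without wt replicate 1 or 2 the count was 83 or 99, and without kai replicate 1 or 2 it was 97 or 67. The calls of atpA (adjusted p = 0.0767 to 0.158), slr5053 (0.0697 to 0.421) and slr1915 (0.0533 to 0.072) were lost without any of the 4 libraries. So were those of slr1667 without replicate 2 of either strain (0.0799 and 0.101), rbcL without wt replicate 1 or kai replicate 2 (0.0641 and 0.0692) and apcA without kai replicate 2 (0.052). Of 49 ribosomal protein genes 13 fell, 25 adjusted over the list alone (median -1.03, camera adjusted p = 1.03e-17). Carbon uptake had 9 of 14 lower, 11 over the list alone (median -1.68, 5.44e-15), ATP synthase 6 of 10, then 9 (median -1.79), phycobilisome 5 of 15, then 7 (median -0.96), Rubisco and carboxysome 4 of 13, then 6 (median -1.29), and cytochrome b6f and carriers 2 of 11, then 3, with petJ 11.4-fold lower. Chaperones had 6 of 11 higher, 7 over the list alone (median 1.17, 9.81e-12), and dark-induced genes 3 of 5, then 4 (median 1.56). Pili had 5 of 34 higher and 1 lower, 6 and 1 over the list alone, with the major pilin pilA1 3.88-fold lower. All of these and phosphate acquisition (1 of 11 lower, 3 over the list alone) passed with an estimated correlation too, while chlorophyll and haem synthesis (1 of 19 lower, camera 0.022, or 0.0809 without wt replicate 2) did not (adjusted p = 0.19). By category, 6 of 16 chaperone genes were higher (0.5 expected, Fisher adjusted p = 0.000196), and 14 of 62 genes of ribosomal proteins were lower (2 expected, 5.15e-07).

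**Figure D4:**
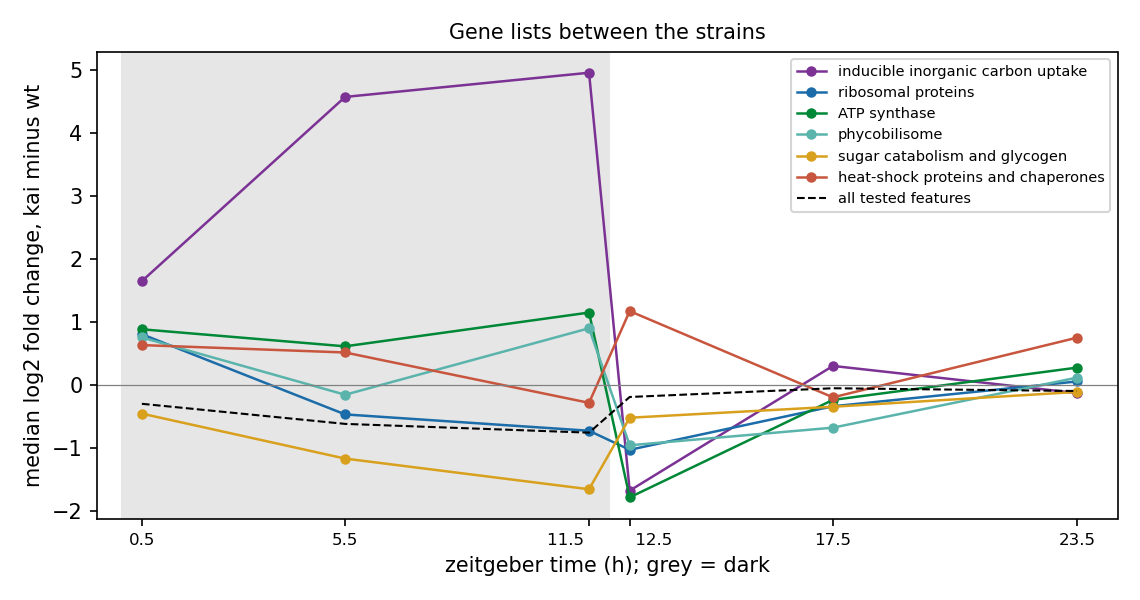
Median log2 fold change of kai against wt for 6 gene lists (solid lines) and for all tested features (dashed line) by zeitgeber time in hours, with darkness in grey. Carbon uptake has a median of 4.57 at ZT 5.5, 4.95 at ZT 11.5 and -1.68 at ZT 12.5.

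In the middle of the light period, 32 features were past the threshold. The exchangeable electron carriers of photosynthesis moved in opposite directions: petE for plastocyanin was 2.77-fold higher in kai (adjusted p = 0.012), and petJ for cytochrome c553 23.97-fold lower, at 128 ± 115 against 2437 ± 661 (adjusted p = 0.00068). The sugar-catabolism regulator sigE was 22.4-fold lower (609 ± 178 against 13445 ± 1558) and gap1 6.25-fold lower, while sigC was 2.24-fold and cmpC 2.47-fold higher. The hypothetical gene slr1152 was 11.5-fold higher, with slr0967 and sll1621 next (log2 fold changes 1.96 and 1.59). The short gene ssr2062 was 39.5-fold, sll0450 10.2-fold and sll7089 lower (-3.16). limma called 12 higher and 20 lower at ZT 17.5, 3 of the lower non-coding, and edgeR 38 and 39, with 30 shared. Of the calls 37.5% were higher, a share that became 49.4% with edgeR, 51.2% with DESeq2 and 26.7% with total-count scaling. Without wt replicate 1 or 2 the count was 9 or 10, and without kai replicate 1 or 2 it was 16 or 9. The call of sigC was lost without any of the 4 libraries (adjusted p = 0.0513 to 0.239), those of petE (0.11 to 0.218) and cmpC (0.0963 to 0.212) without any but kai replicate 1, slr0967 without any but wt replicate 1 (0.165 to 0.466), and ssr2062 without wt replicate 1 or kai replicate 2 (0.0962 and 0.141).

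As lists at ZT 17.5, phosphate acquisition was lower with 3 of 11 genes, 4 over the list alone, among them pstS1 (3.42-fold) and phoA (4.29-fold; median -1.62, camera adjusted p = 7.71e-07). Phycobilisome, ribosomal and photosystem I genes shifted lower as lists (medians -0.68, -0.34 and -0.67) and pili, nitrogen assimilation and high-light genes higher (0.35, 0.54 and 0.50), although limma called 0 of their genes singly. At an unadjusted p under 0.05, 6 phycobilisome, 6 ribosomal and 3 photosystem I genes were lower, and 10 pili, 2 nitrogen and 4 high-light genes higher; edgeR called 1 pili and 2 nitrogen genes higher and 0 of the others. Adjusted over the list alone, 3 phycobilisome and 2 photosystem I genes fell, and 4 pili genes and 1 high-light gene rose. Chaperones had 2 of 11 lower, 4 over the list alone (dnaK2 2.42-fold, groES 2.88-fold; median -0.20). The calls of groES and phoA were lost without any of the 4 libraries (adjusted p = 0.157 to 0.301 and 0.0962 to 0.274), pstS1 without any but wt replicate 1 (0.0513 to 0.183), and dnaK2 without wt replicate 1 or kai replicate 2 (0.071 and 0.0959). All of these held with an estimated correlation, whereas carbon uptake (1 of 14 higher, median 0.30, or -0.016 after quantile rescaling), sugar catabolism (1 of 21 lower) and the dark-induced genes (0 of 5) did not (adjusted p = 0.17, 0.099 and 0.11). With camera these 3 calls were lost without kai replicate 1 (0.0676), kai replicate 2 (0.0615) and wt replicate 2 (0.0556), respectively.

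Late in the light period, photoprotection and chaperone genes were higher in kai. ocp averaged 81804 ± 13757 against 18715 ± 2290 (4.36-fold, adjusted p = 0.00015), hspA was 4.83-fold and htpG 3.55-fold higher, and sll1483, slr0967, slr1152 and slr1622 rose by log2 fold changes of 2.42, 2.37, 2.20 and 1.91. Sugar-catabolism genes were lower again, with sigE at 14.2-fold, gap1 at 4.46-fold, pfkA1 at 4.36-fold and gnd at 3.71-fold. ssr2062 was 63.6-fold lower, and sll5057, sll1330 and sll7064 had log2 fold changes of -3.84, -3.50 and -3.43. At ZT 23.5, 70 features were higher and 51 lower, 2 and 11 of them non-coding; edgeR called 91 and 65, with 113 shared. Of the calls 57.9% were higher, a share that became 37.5% after quantile rescaling, 47.1% with DESeq2 and 19.2% with total-count scaling. Without wt replicate 1 or 2 the count was 52 or 32, and without kai replicate 2 it was 46. The call of slr1622 was lost without any of the 4 libraries (adjusted p = 0.0592 to 0.426), and those of pfkA1 (0.0549 to 0.135), gnd (0.0688 to 0.128), sll5057 (0.0515 to 0.0579) and sll7064 (0.0707 to 0.126) without any but kai replicate 1. Those of sll1483 were lost without any but wt replicate 1 (0.0851 to 0.176), of sll1330 without replicate 2 of either strain (0.431 and 0.451), and of slr0967 without wt replicate 1 or kai replicate 2 (0.0669 and 0.0931). Chaperones had 4 of 11 higher, 5 over the list alone (median 0.75, camera adjusted p = 1.40e-08), dark-induced genes 2 of 5, then 3 (median 1.33), and high-light genes 2 of 11, then 3 (median 0.43, camera 0.0617 without kai replicate 1), with either correlation. Rubisco and carboxysome had 1 of 13 higher (camera 0.023, or 0.0714 and 0.254 without kai replicate 1 and wt replicate 2), a call lost with an estimated correlation (adjusted p = 0.063). Sugar catabolism had 3 of 21 lower, 1 higher and 4 lower over the list alone, and was not past the threshold as a list.

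Averaged over the 6 times, single genes of carbon uptake and chaperones were higher in kai and single genes of sugar catabolism lower. At single times carbon uptake genes were lower at ZT 12.5 and the chaperone genes dnaK2 and groES at ZT 17.5. The chaperone and sugar-catabolism lists lost the call with an estimated correlation (adjusted p = 0.084 and 0.18). cmpD was 6.21-fold (log2 fold change 2.63 ± 0.138 SE, adjusted p = 1.34e-09), cmpC 4.96-fold, porB 4.67-fold and hspA 4.72-fold higher. The highest mean changes were those of slr1594, a PatA-type response regulator (7.07-fold, adjusted p = 0.00012), the chromate transporter slr5038 and its neighbour slr5037 (2.72 and 2.65 on the log2 scale), slr1078 (5.87-fold), slr1084, slr0967 (4.62-fold), the nucleoside diphosphate kinase sll1852 and sll0572. Lower were sigE (5.50-fold, -2.46 ± 0.202, adjusted p = 1.69e-07), gap1 (-2.59) and pfkA1 (2.14-fold). Below the deleted clock genes came slr7098, at 44.9 ± 33.9 against 606 ± 292 (17.6-fold), slr5055, sll7087 (12.99-fold), ssr2062 (10.7-fold), sll1552, slr7094, slr1732 (8.42-fold), slr7097 and slr7100. Among non-coding features gorapncrna194 averaged 0.371 in kai and 76.2 in wt, gorapncrna181 0.181 and 25.1, and klaehnncrna199 was 2.84-fold higher (7090 against 1466, adjusted p = 9.32e-08). At all 6 times slr0518 was higher, and kaiC1, gorapncrna194 and sll0450 were lower.

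Over all times 424 features were higher and 819 lower, 42 and 144 of them non-coding; edgeR called 483 and 726, with 1070 shared. The higher share of 34.1% became 50% after quantile rescaling and 6.1% with total-count scaling. Carbon uptake had 13 of 14 higher, 14 over the list alone (median 1.501, camera adjusted p = 8.61e-19), dark-induced genes 5 of 5 (median 1.25), photosystem I 4 higher and 1 lower of 12 (median 0.15, or -0.080 after quantile rescaling and -0.53 with total-count scaling) and phosphate acquisition 6 of 11 lower, 7 over the list alone (median -1.27), each with either correlation. Chaperones (4 higher and 1 lower of 11, median 0.13, or -0.053 after quantile rescaling and -0.55 with total-count scaling), sugar catabolism (8 of 21 lower, 9 over the list alone, median -0.80) and high-light genes (4 higher and 1 lower of 11, median 0.23, or -0.45 with total-count scaling; camera 0.0574 without kai ZT 11.5 replicate 1) lost the call with an estimated correlation (adjusted p = 0.084, 0.18 and 0.079). Not past the threshold as lists were ribosomal proteins (6 higher and 16 lower of 49), pili (9 and 8 of 34), photosystem II (6 and 3 of 26), chlorophyll and haem synthesis (2 and 7 of 19), nitrogen assimilation (4 and 3 of 19), NDH-1 (4 and 3 of 16), phycobilisome (5 and 4 of 15; median -0.14, test direction higher), Rubisco and carboxysome (2 and 1 of 13), cytochrome b6f (1 and 4 of 11), ATP synthase (1 and 0 of 10), sigma factors (4 and 3 of 9), iron (2 and 1 of 9), oxidases (0 and 4 of 8), the remaining clock genes (1 and 2 of 8) and hydrogenase (0 and 2 of 5).

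Genes of the plasmid locus-tag series were lower more often than expected over all times: 36 of 69 tested genes of the 7000 series (14.4 expected, Fisher adjusted p = 6.93e-07, 1 higher) and 34 of 91 of the 5000 series (19 expected, 0.00997). The 5000 series moved both ways, since its genes slr5037 and slr5038 were among the highest over all times. At single times 24 genes of the 7000 series were lower at ZT 5.5 (11.4 expected, 0.016), 4 at ZT 17.5 (0.4 expected, 0.038) and 6 at ZT 23.5 (0.9 expected, 0.0087). Strain differences were shared between times: ZT 5.5 and 11.5 shared 283 higher features (46.8 expected, adjusted p = 1.88e-214) and 334 lower (185 expected, 1.14e-41), and ZT 0.5 and 5.5 shared 110 higher (19.4 expected). ZT 11.5 and 12.5 shared 30 higher features (14.9 expected, adjusted p = 0.000109) but lower ones no more than expected (27 against 30.6, adjusted p = 0.81). Times far apart shared features too, with 38 higher and 22 lower at both ZT 0.5 and ZT 23.5 (3.9 and 2.8 expected). ZT 17.5 and 23.5 shared 8 higher and 12 lower features (0.2 and 0.3 expected). Fisher's exact test takes features as independent, though neighbouring genes can move together. All times also share each feature's spread from a single fit. The expected numbers and p values therefore do not measure chance sharing alone.

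The return of light was followed from ZT 11.5 to ZT 12.5 in each strain. In wt, atpD rose 42.8-fold, apcA 9.55-fold, rbcL 6.51-fold and rpl22 5.81-fold, and all 10 ATP synthase genes and 41 of 49 ribosomal protein genes rose, with 0 falling (medians 4.19 and 2.36). Genes that fell in wt included hspA (65.8-fold), lexA (7.89-fold), the sigma factor genes sigH (71.3-fold) and sigC (16.2-fold), the pilin-like gene slr1668 (172-fold), pilA5 (47.5-fold) and slr1667 (331-fold). In wt 9 of 14 carbon uptake genes rose (median 1.74, a camera call lost with an estimated correlation, adjusted p = 0.19), whereas in kai all 14 fell (median -5.12, adjusted p = 0.0093 with an estimated correlation). The kai response also lowered sll5036 from 50532 to 24.4 normalised counts, sll1598 from 22312 ± 2587 to 17.5 ± 1.49 (1207-fold), its partner sll1599 and the carbamate kinase sll0573. Raised from 0 reads in kai were slr0864, slr1821, sll0867, slr1420, the enoyl reductase slr1051 and slr0959, by at least 25.7-, 24.1-, 20.99-, 17.4-, 16.7- and 16.5-fold, and in wt the precorrin isomerase sll0916 and slr2007, by at least 67.0- and 40.2-fold.

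In wt 858 features rose and 527 fell on lights on (edgeR 814 and 754, 1224 shared), and in kai 1604 and 589 (edgeR 935 and 613, 1497 shared). In simulated data limma made 56 false calls for lights on in kai and 1 in wt, and edgeR 0 and 1. Of the 1604, 692 had 0 reads in both kai libraries at ZT 11.5. In wt, 89 of the 858 had 0 reads in both libraries of that time. Some of these rises in kai ended under the floor of ZT 11.5, such as psaK1 and sigI (0.70 and 0.20 times the floor), so they were not measurable. Others did not, such as dnaK3 (at least 13.7-fold). How many of the 692 ended under the floor was not counted. The rising share was 61.9% in wt and 73.1% in kai; it was 50.7% in wt with upper-quartile scaling, 49.7% and 54.5% after quantile rescaling, 60.4% in kai with edgeR and 59.9% with DESeq2, and 84.3% and 93% with total-count scaling. The strains shared 508 rising (364.8 expected) and 316 falling features (82.3 expected, adjusted p = 1.61e-149). Lists past the threshold with either correlation in wt were ribosomal proteins (adjusted p = 0.0019 with the estimated one), ATP synthase (0.030), NDH-1 (11 higher and 1 lower of 16, 0.033), phycobilisome (11 of 15 higher, 0.014), Rubisco and carboxysome (9 of 13 higher, 0.014), pili (1 higher and 13 lower of 34, median -0.98, or 0.055 with total-count scaling, 0.0059), sigma factors (3 higher and 6 lower of 9, 0.026) and dark-induced genes (4 of 5 lower, 0.014). Chlorophyll and haem synthesis (11 higher and 2 lower of 19) and iron genes (3 of 9 lower) lost the call (adjusted p = 0.19 and 0.13), and with camera without wt ZT 11.5 replicate 2 (0.0607) and without wt ZT 11.5 replicate 1 or wt ZT 12.5 replicate 2 (0.0538 and 0.0697). In kai, ribosomal proteins (35 higher and 2 lower), NDH-1 (12 and 1, median 3.58, or 2.13 with genes at their bound), chaperones (8 and 1 of 11) and dark-induced genes (1 and 3) lost it (adjusted p = 0.20 each).

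The lights-on response itself differed between the strains for 1065 features, 683 with a higher and 382 with a lower change in kai (edgeR 624 and 347, 829 shared). The carbon uptake list differed by a median of -6.74 on the log2 scale (14 of 14 lower, camera adjusted p = 1.00e-22), with cmpC at -7.54, ndhD3 at -6.75 and porB at -7.72. ATP synthase (8 of 10 lower, atpD -5.54), phycobilisome (8 of 15 lower and 1 higher, cpcA -4.50), Rubisco and carboxysome (5 of 13 lower, ccmM -2.97) and photosystem I (6 of 12 lower and 1 higher, psaA -4.01; median -1.10, or 0.20 with total-count scaling) had a lower change in kai than in wt, and chaperones a higher one (8 of 11 higher, clpB1 3.16, groEL2 2.21), each with either correlation. Ribosomal proteins (2 higher and 9 lower, adjusted p = 0.072), photosystem II (1 and 7, 0.38) and pili (13 and 2, 0.10) lost the call with an estimated correlation. Single genes with large differences were sll0218 (-9.38 ± 0.896, adjusted p = 1.50e-06) and slr1087 (-8.98). The higher share of 64.1% became 49.8% with DESeq2 and 85.8% with total-count scaling.

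**Figure D5:**
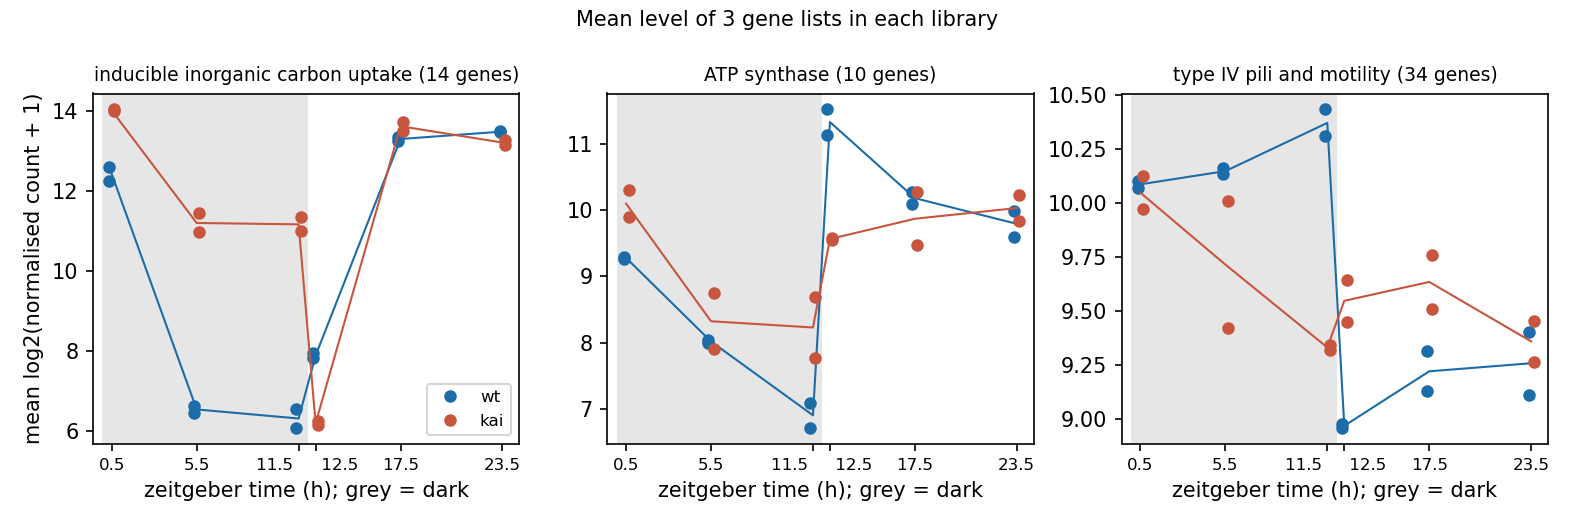
Mean log2 of the normalised count plus 1 over the genes of carbon uptake, ATP synthase and pili in each library by zeitgeber time in hours, for wt and kai, with lines for the group means. For carbon uptake, wt libraries fall to 6.63 and 6.46 at ZT 5.5 while kai libraries are at 10.97 and 11.44, and at ZT 12.5 kai is at 6.26 and 6.15.

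The course of darkness was followed from ZT 0.5 to ZT 11.5. In wt all 14 carbon uptake genes fell (median -6.12, camera adjusted p = 3.22e-35), with sbtB going from 4040 ± 821 to 16.1 ± 0.651 (234-fold, adjusted p = 1.66e-09), porB falling 176-fold, cmpA 152-fold, cmpC 65.6-fold and ndhD3 38.9-fold. Photosystem I fell with 9 of 12 genes (median -1.64, psaD 5.03-fold) and the phycobilisome with 8 of 15 (median -1.22, or -0.70 with genes at their bound; cpcD 11.7-fold, cpcA -2.81 on the log2 scale). The chaperone gene hspA rose in wt from 1602 ± 11.2 to 71432 ± 228 (44.6-fold), the stress regulator slr1738 20.3-fold and sll5036 16.3-fold, and slr7052 by at least 24.2-fold (a call lost without any of the 4 libraries, adjusted p = 0.0968 to 0.185), while sll0218 fell 216-fold and sll0743 at least 32.6-fold. In kai 11 of 14 carbon uptake genes fell (median -3.05), a call lost with an estimated correlation (adjusted p = 0.11), and slr0588 rose from 31.4 ± 12.2 to 12376 ± 2215 (393-fold), slr0521 340-fold and ssl5031 317-fold, with slr5040, sll5028 and ssl0606 at least 110-, 89.0- and 78.2-fold higher. Genes that kai no longer showed at ZT 11.5 included ndhJ (at least 8.94-fold lower), ssr0693 (15.7), sll1704 (9.45), sll5079 (9.16), slr1906 (6.26) and slr1067 (5.66).

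In wt 196 features rose and 286 fell in darkness (edgeR 190 and 340, 428 shared), and in kai 468 and 1035 (edgeR 362 and 797, 982 shared); 462 of the 1035 had 0 reads at ZT 11.5, and 296 of these started under the floor. For the dark course in simulated data, limma made 37 false calls in kai and 0 in wt, and edgeR 0 in each. The rising share of 40.7% in wt was 12.7% with total-count scaling, and that of 31.1% in kai was 47.8% after quantile rescaling, 51.6% with DESeq2 and 11.1% with total-count scaling. Without wt ZT 0.5 replicate 1 or 2 the wt count was 223 or 237. Lists called in wt but lost with an estimated correlation were ATP synthase (6 of 10 lower, adjusted p = 0.052), chaperones (4 higher and 1 lower of 11, 0.052) and photosystem II (1 higher and 6 lower of 26, 0.26). Lost too were Rubisco, NDH-1, sugar catabolism, hydrogenase, sigma factors, dark-induced genes (2 higher and 1 lower of 5, median 0.33, or -0.28 under total-count scaling) and phosphate acquisition. In kai, NDH-1 (13 of 16 lower, median -3.00, or -1.91 with genes at their bound; 0.11), ribosomal proteins (2 higher and 22 lower of 49, 0.13), oxidases (5 of 8 lower, 0.14), hydrogenase (4 of 5 lower, 0.28), ATP synthase (8 of 10 lower, 0.33) and dark-induced genes (3 of 5 higher, median -0.31 under total-count scaling, 0.13) lost the call.

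The dark course differed between the strains for 731 features, 273 with a higher and 458 with a lower change in kai (edgeR 217 and 418, 515 shared). Carbon uptake differed by a median of 3.05 (11 of 14 higher, 12 over the list alone, camera adjusted p = 5.88e-14, 0.014 with an estimated correlation), led by cmpC at 5.06 and cmpD at 4.71. Chaperones (6 of 11 lower, adjusted p = 0.19), NDH-1 (7 of 16 lower, 0.19), ribosomal proteins (2 higher and 12 lower, 0.20) and oxidases (2 of 8 lower, 0.19) lost the call with an estimated correlation. The higher share of 37.3% became 51.6% with DESeq2 and 24.6% with total-count scaling. Without wt ZT 0.5 replicate 1 or 2 the count was 482 or 480, and without kai ZT 11.5 replicate 1 or 2 it was 1196 or 1151.

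Time itself was past the threshold for 1298 features in wt (edgeR 1558, 1185 shared) and 2555 in kai (edgeR 2356, 2162 shared). The largest F values in wt belonged to ssr2787 (457.65, adjusted p = 3.69e-13), ndhD3 (374.32), cmpC (367.3), hspA (309.67), porB (307.75) and flv2 (297.67). In kai they belonged to slr0518 (401.55, adjusted p = 8.31e-13), hspA (382.94), cmpC (349.38), dnaK2 (347.58), sll1086 and slr6100. In simulated data limma made 45 false calls for time in kai and 1 in wt, and edgeR 3 and 1. With 2 replicates per group, the adjusted p values of limma rest on a spread pooled over all groups of these samples, not on that of the groups compared.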

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

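The tests of library scaling, the thinning at ZT 5.5 and both tests of the 7000 series were chosen only after the result was seen.

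The effect of the strain differed between times for 1131 features by the interaction test. The response to lights on differed between the strains for 1065 features and the dark course for 731. The median log2 difference of the carbon uptake list was -6.74 in the response to lights on and 3.05 in the dark course. Each of these was singled out because the difference between groups was itself tested and passed. For the strain effect over all times, the libraries were split anew within each time. Of 100 splits, 1, the real one, gave as many features, with 1243 against at most 816 in any other split. This argues against chance only if the libraries are independent. Whether equal replicate numbers mark the same culture is not stated, and if they do, the splits cannot exclude chance.

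The 1575 features that differed at ZT 11.5 came from libraries of unequal depth. Thinning cut the wt libraries to 14.7% and 10.3% of their reads. It matched their size factors, not their read totals, to those of the kai libraries. A median of 1449.5 features over 10 draws (1429 to 1479) remained, so the count stayed high at matched size factors. Thinning adds counting noise to wt, which can itself make calls, and leaves the 0 reads of kai in place. It therefore cannot tell how much of the count unequal depth accounts for. Under upper-quartile, quantile and total-count scaling limma called 1585, 1277 and 1998, and edgeR, which changes the test as well as the scaling, called 1225, the lowest of these 4, which argues against the scaling as the whole cause of the count, though not of its split into higher and lower. Open remain the low depth shared by all comparisons with these kai libraries and the 111 false calls of limma in simulated data, against 0 for edgeR. Those data did not carry an unequal spread between groups beyond counting noise. The deletion itself also stays open as an explanation, and it was not tested further.

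Carbon uptake genes were higher in kai at ZT 5.5 and ZT 11.5, and from ZT 0.5 to ZT 11.5 their median change was -3.05 in kai, where 11 of 14 fell, and -6.12 in wt, where all 14 fell. The lowest median log2 fold change of kai against wt under these 4 scalings was 2.87, at ZT 5.5 with total-count scaling, which argues against scaling as the whole cause. The median after thinning was 5.16 at ZT 11.5 and 4.70 at ZT 5.5 (4.50 to 4.79 over 10 draws, where wt kept 32.1% and 26.99% of its reads), with at least 13 of 14 genes past the threshold at ZT 5.5. The difference thus remained at matched size factors. Thinning lowers low wt levels on the log scale, which raises kai against wt, so the median could hardly fall. The thinning therefore cannot decide on unequal depth. The deletion itself stays open as an explanation, and no measurement of carbon or redox state exists in these data.

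Genes of the 7000 series were lower in kai over all times. The 36 genes past the threshold kept a median of 37.2% of their wt level (SE 5.09), above the 7.14% of kaiA, 10.3% of kaiB1 and 1.22% of kaiC1, or 36.5% against 3.18%, 1.59% and 1.33% without replicate 1 of kai at ZT 5.5, which argues against deletion of the set as a whole. Single genes were not tested: slr7098 and slr7099 kept 7.42% and 7.98%, or 7.75% and 8.71% without that library, and 13 of the 36 had reads in all 12 kai libraries. In 3 parts of 23 tested genes each, in locus-tag order, the medians were -0.79, -1.37 and -2.07. The last lay below the first by a log2 difference of -1.28 (SE 0.321, 2000 bootstrap draws). If genes are independent, this argues against a single lower copy number of the whole plasmid as the whole cause. Neighbouring genes can move together, so the SE may be too small. A lower copy number may still contribute, and so could loss of part of the plasmid in some of the cells, which remain open without DNA reads.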

How the results depend on the processing

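Total-count scaling and leaving out the kai libraries of ZT 5.5 and ZT 11.5 were chosen only after the result was seen. Of the named gene results, 309 of 441 kept direction and side of the threshold in every alternative run, and of 333 past the threshold 251 stayed past it in every one. Over all alternatives, gene results were the same in 7779 cases, weaker in 273, stronger in 121 and reversed in 12, and list results 3257, 79, 137 and 3. Counts stayed within 1.5 times the reported count in 299 cases and moved beyond it in 56.

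Leaving out each library in turn gave 123 to 237 features at ZT 0.5, 592 to 1354 at ZT 5.5, 67 to 99 at ZT 12.5, 9 to 16 at ZT 17.5 and 32 to 84 at ZT 23.5. It gave 223 to 436 for the dark course in wt, 480 to 1196 for its difference between the strains and 951 to 1756 for the interaction. The cause of the lower and of the higher counts was not tested. At ZT 11.5 (1321 to 1807) and over all times (1065 to 1727) the counts stayed within 1.5 times.

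DESeq2 called fewer at ZT 11.5 (1386) and in kai for lights on (1762) and the dark course (1292), and more elsewhere, with 850 at ZT 0.5, 557 at ZT 12.5, 164 at ZT 17.5, 272 at ZT 23.5, 851 for the dark course in wt, 1785 for the interaction and 2172 for time in wt. edgeR called 77 at ZT 17.5. With only the 4 libraries of a time the counts were 765 at ZT 0.5, 661 at ZT 5.5, 572 at ZT 11.5, 1032 at ZT 12.5, 72 at ZT 17.5 and 37 at ZT 23.5. Quantile rescaling gave 375 at ZT 12.5, 68 at ZT 17.5 and 482 for the difference in dark course. With replicate as a block, which treats equal replicate numbers as a pairing, ZT 17.5 had 54. Total-count scaling gave 718 at ZT 0.5, 2222 at ZT 5.5 and 2460 over all times. Without the kai libraries of ZT 5.5 and ZT 11.5 the counts were 957 at ZT 0.5, 529 at ZT 12.5, 111 at ZT 17.5, 292 at ZT 23.5, 715 over all times, 2211 for lights on in wt, 1017 for the dark course in wt and 2290 for time in wt. Of the 7 lists past the threshold over all times, 4 were so with an estimated correlation and 13 with fry, which asks another question. For the other shifts the cause was not tested.

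With total-count scaling sasA reversed to -1.22 at ZT 5.5, -0.71 at ZT 11.5, -0.32 over all times and 0.94 on lights on in kai, and kaiA3 to -0.56 over all times and 2.22 on lights on in kai. Quantile rescaling reversed kaiB3 over all times (0.087) and kaiB1 and kaiC1 on lights on in kai (-2.45 and -0.90), as well as psaB at ZT 0.5 (-0.53) and cpcA at ZT 5.5 (-0.10). Without kai ZT 11.5 replicate 2, cikA on lights on in kai went to -0.053, and without replicate 1 it was 7.11. The sigma factor list at ZT 11.5 went down under fry (median -0.76, adjusted p = 0.0025). Without the kai libraries of ZT 5.5 and ZT 11.5 the photosystem I list turned from 0.15 to -0.11 over all times, and the test direction of the phycobilisome list turned to lower (median -0.14, then -0.32). The reversals with total-count scaling follow from its shift of all features of a library by the same factor, and for the others the cause was not tested. Depth limits what is seen in kai at ZT 11.5, where 3 reads equal 53.3 and 48.2 normalised counts.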

Other observations

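Some genes with neighbouring locus tags were higher in kai in darkness. They were picked after their values were seen, and neighbours that did not differ were not counted. The sulfide-quinone reductase gene sll5036 of the 5000 series and its neighbours sll5034 and sll5033 were higher in kai at each dark time: sll5034 by log2 fold changes of 6.02, 4.80 and 4.83 at ZT 0.5, 5.5 and 11.5, sll5033 by 4.30, 4.69 and 5.58, and sll5036 by 6.74, 4.75 and 4.31. Between slr1073 and slr1087, slr1076 differed by 5.77 and 5.58 at ZT 5.5 and 11.5, slr1077 by 5.15 and 6.09, slr1085 by 5.37 and 7.25 and slr1087 by 5.97 and 8.49. Genes for flavodiiron proteins, which pass electrons to oxygen, flank sll0218 by locus tag: flv4 differed by 4.34 and 5.46, sll0218 by 7.26 and 8.83, and flv2 by 4.81 and 5.18. All of these are members of the carbon uptake list, so they are no separate result. Manganese transport genes sll1598 (6.27 and 6.04) and sll1599 (5.47 and 7.75) were higher too, the ZT 5.5 call of sll1599 being lost without any of the 4 libraries (adjusted p = 0.0674 to 0.147) and the ZT 11.5 call without wt replicate 1 (0.0522).

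The short gene ssr2062 was lower, with log2 fold changes of -4.87 at ZT 11.5, -5.30 at ZT 17.5 and -5.99 at ZT 23.5; the ZT 17.5 call was lost without wt replicate 1 or kai replicate 2 (adjusted p = 0.0962 and 0.141). sigE was lower at ZT 0.5 (-2.39), 11.5 (-1.49), 12.5 (-2.06), 17.5 (-4.49) and 23.5 (-3.83), and not past the threshold at ZT 5.5 (-0.50, adjusted p = 0.50). Its calls were lost at ZT 12.5 without any of the 4 libraries (0.0895 to 0.17), at ZT 11.5 without any but kai replicate 1 (0.0521 to 0.117) and at ZT 0.5 without replicate 1 of either strain (0.0646 and 0.0761).

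Of the 24 libraries, 13 correlated best across features with a library other than their partner, 3 of them with one of the other strain. These 3 were replicate 1 of kai at ZT 5.5 (0.801 with replicate 2 of wt at ZT 0.5, 0.768 with its partner), at ZT 17.5 (0.959 with replicate 1 of wt at ZT 17.5, 0.955 with its partner) and at ZT 23.5 (0.941 with replicate 1 of wt at ZT 23.5, 0.930 with its partner).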
